A study of Mus musculus with 2 samples.

How the data were processed

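Cells of the embryonic day 14.5 mouse pancreas with the genotype given as Ngn3 negative were profiled in 2 samples. The labels' protocols describe sorting for low and high Ngn3-eGFP, encapsulation in inDrop droplets and CEL-Seq linear amplification, which reads tags near the 3′ end of each transcript. The series text speaks of 2 mice, but the labels tie no sample to an animal, and no library of another genotype belongs to the series. The authors deposited, for each sample, a table of UMI counts with 1 line per gene and 1 column per barcode, and the tables hold whole numbers throughout. The build was GRCm38, per the submitters' processing notes. The aligner, the counting program, the gene annotation, the collapse of UMIs and the authors' own choice of barcodes are not given in the sources used here. The tables name genes by symbol.

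The deposited tables hold 618 and 1115 barcodes over 25507 genes. Barcodes with at least 1000 UMIs, at least 500 genes and under 20% mitochondrial UMIs were used, which left out 17 barcodes of sample 1 and 10 of sample 2. Scrublet, run per sample in scanpy 1.11.5, called 6 and 11 of the others doublets, and these were left out as well. The 595 and 1094 cells used entered a joint Leiden clustering (resolution 1, 2000 variable genes, 30 components, 15 neighbours) without integration of the samples. Mitochondrial, ribosomal, cell cycle and sex-linked genes and Neurog3 were kept out of the variable genes. The counts of each cell were split at random into 50% for clustering and 50% for testing, so that most comparisons did not test the counts that made the classes.

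Clusters were named from marker lists fixed before the data were examined. A marker supported a name where it reached 50 CPM and 3 times the level at the 25th percentile of clusters, at least 3 such markers were needed, and a cluster whose 10 top genes held more markers of another type than of its own stayed unnamed. These limits were set after the marker levels per cluster had been seen. Division of the unnamed cluster 2 at several resolutions was tried and not used. The marker genes of a class named it, and their differences are not independent results.

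Counts were summed per sample and class, which gives 4 sums per comparison and 1 residual degree of freedom. edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood test) in R 4.3.3 was fitted with sample as a block, with Benjamini-Hochberg adjustment at 0.05. Sums with the same sample number come from the same sample, which is where the pairing comes from. The labels do not exclude pools, so paired sums need not come from the same animals. The comparison of cells with and without a Neurog3 UMI used all UMIs with Neurog3 left out. Cells without a UMI were to be drawn from the same decile of depth, up to 5 per cell with one, but this took all of the 187 and 96 such cells, so the planned matching removed no difference in depth. An equal number of cells per decile was therefore added as an alternative after seeing the data. Gene lists (15, fixed before the data were examined) were tested with camera in limma 3.58.1 with the preset correlation of 0.01, and with an estimated correlation and fry beside it. The estimated correlation rests on the 1 residual degree of freedom, so that form had little power to call any list. A list it did not call is therefore left undecided by it. DESeq2 1.42.0, run on all genes with a count and not on the filtered set, served as an alternative test.

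Levels are given as CPM (counts scaled to the summed UMIs) with exact Poisson intervals, and shares of cells with exact Clopper-Pearson intervals, at 95%. These cover counting error only. Shares with a UMI are also given after thinning each cell to 2500 UMIs, with shallower cells left out. A gene at 0 counts was given a floor of 3 counts over both samples. Fold changes are given as log2 values ± SE of the fit over the 2 samples. A sample's own log2 value is scaled to the summed UMIs without TMM, so it can be offset from the fitted value in both samples. The test was checked on simulated counts with 200 genes changed by known folds; the first simulation had put in no change and was corrected, with the test itself left as it was. Of genes changed 2-fold and 4-fold, the test called 47.7% and 91.4% at the sums of the tip and trunk comparison, 0% and 17.4% at those of the endocrine-like comparison, 32.4% and 84.8% at those of the clusters 6 and 7, and 64.3% and 92.0% at those of the Neurog3 UMI comparison. False calls were 2.86%, 0%, 4.24% and 2.55% of the calls. The simulation gave all genes of a comparison the same spread. These percentages therefore hold under a shared spread. They cannot show how the test behaves where genes differ in spread, since no such counts were simulated.

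The rule for named genes, fixed before the data were examined, took per comparison the 10 largest changes in each direction with an adjusted p under 0.05, the same direction in both samples and at least 50 CPM in the class where higher, up to 4 members of each list with the smallest p, and 12 genes always. The genes printed are a part of that set picked for length, and Nprl3, which falls outside it; some genes of the set are counted in the totals but not reported here by name. Alternatives covered other size factors, another test, no filter on low counts, no block, all classes in 1 fit, 2000 UMIs, doublets kept, another split of the UMIs, all UMIs, resolutions of 0.5 and 2, genes centred within each sample, and each sample left out. Alternatives chosen after seeing the data are named in the closing section. Genotypes were not compared, since the series holds 1.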

Results

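Single-cell UMI counts were collected from sorted Ngn3-eGFP low and high cells of the E14.5 pancreas of Ngn3 negative mice, in 1 group of 2 samples. The labels do not say whether a sample is an animal, a pool or a sort fraction, so no difference or agreement between the samples can be assigned to animals. Sample 1 held 618 barcodes with 5388613 UMIs in all, and sample 2 held 1115 barcodes with 9097670. The median depth was 7486 UMIs per barcode in sample 1 and 7500 in sample 2. The cells used numbered 595 and 1094. Neurog3 encodes the transcription factor that starts endocrine differentiation, and the samples allow the classes of sorted cells to be compared within this genotype, not with wild-type tissue.

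Neurog3 stood highest per UMI in endocrine progenitor-like and trunk/duct-like cells. In trunk/duct-like cells Neurog3 stood at 157 CPM in sample 1 (95% interval 142 to 175) and 207 CPM in sample 2 (179 to 238). The trunk/duct-like levels were 155 and 135 CPM with classes from all UMIs and 147 and 108 CPM at resolution 2, where unnamed cells of sample 2 held 239 and 345 CPM. Trunk/duct-like and unnamed cells added together held 144 and 182 CPM, 145 and 205 with all UMIs, and 147 and 186 at resolution 2. With genes centred within each sample, trunk/duct-like cells held 150 and 193 CPM. The 5 and 13 endocrine progenitor-like cells held 252 CPM (92.6 to 549) and 496 CPM (332 to 712), and the unnamed cells 87.5 CPM (64.1 to 117) and 66.9 CPM (36.6 to 112). Tip/acinar-like cells held 17.8 and 12.8 CPM (37.5 in sample 1 with genes centred within each sample), and leukocyte-like cells, which should lack the gene, 19.0 and 13.8 CPM. No Neurog3 UMI was seen in the 6 and 7 endothelium-like cells, which allows up to 69.4 and 81.2 CPM by the exact Poisson bound.

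A Neurog3 UMI was present in 44.0% of trunk/duct-like cells of sample 1 (median depth 6807.5 UMIs) and 46.1% of those of sample 2 (4972.5 UMIs). The background share in leukocyte-like cells was 6.25% (7244 UMIs) and 7.04% (4646 UMIs). At 2500 UMIs per cell the trunk/duct-like shares were 25.5% and 31.5%, against 6.67% and 1.41% in leukocyte-like cells, with 44 shallower trunk/duct-like cells of sample 1 left out. The gene lies on chromosome 10 of GRCm38 from 62133090 to 62134763 on the plus strand, with its coding sequence in exon 2 (62133463 to 62134104) and a 3′ UTR from 62134105 to 62134763. The labels do not say which part of the gene was altered, so a 3′ tag checks neither the genotype nor the loss of the protein.

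**Figure D1:**
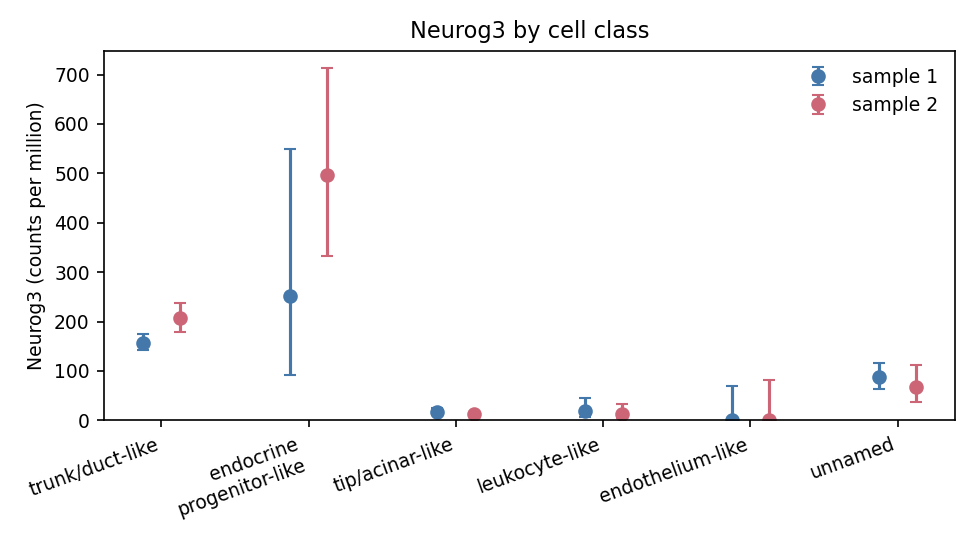
Neurog3 in CPM (vertical axis) for each cell class (horizontal axis), with 1 point per sample and exact 95% Poisson intervals. Trunk/duct-like cells sit at 157 and 207 CPM, and leukocyte-like cells at 19.0 and 13.8 CPM.

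Tip/acinar-like and trunk/duct-like cells made up most of both samples, with more tip/acinar-like cells in sample 2. Tip/acinar-like cells, the tips and early acinar cells of the epithelium, were 27.4% of sample 1 (163 of 595 cells, 23.8% to 31.2%) and 73.1% of sample 2 (800 of 1094, 70.4% to 75.7%). Trunk/duct-like cells, the epithelium from which ducts and endocrine cells form, were 56.1% of sample 1 (334 cells) and 16.3% of sample 2 (178 cells). Leukocyte-like cells made up 5.38% and 6.49%, and their cluster also held the mast cell genes Cpa3, Cma1 and Tpsb2 among its top genes. Endocrine progenitor-like cells were rare, at 0.840% (5 cells) and 1.19% (13 cells), although the sort was for Ngn3-eGFP. An unnamed cluster, with trunk markers, mitotic genes and collagen genes, held 9.24% and 2.29%.

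The clusters behind a class differed between the samples. Of the trunk/duct-like cells, cluster 6 held 304 in sample 1 and 45 in sample 2, and cluster 7 held 30 and 133. Of the tip/acinar-like cells, cluster 0 held 99 in sample 1, while clusters 3, 4, 5 and 10 held 168, 157, 269 and 158 in sample 2. With genes centred within each sample before clustering, tip/acinar-like cells were 42.2% and 44.6%, and 48.6% and 72.8% together with an unnamed cluster that held 14 tip/acinar markers. With classes from all UMIs trunk/duct-like cells were 6.86% of sample 2, and 19.4% together with unnamed clusters that held trunk markers. Shares were not tested, since the samples form 1 group.

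**Figure D2:**
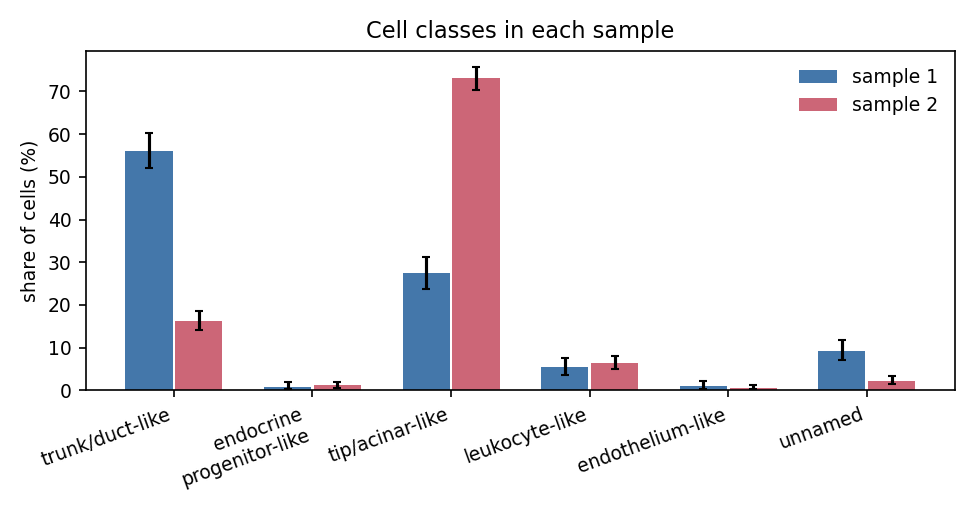
Share of cells in percent (vertical axis) for each class (horizontal axis), with 1 bar per sample and exact 95% Clopper-Pearson intervals. Trunk/duct-like cells are 56.1% of sample 1 and 16.3% of sample 2.

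Islet hormone genes other than Pyy were close to 0 over all cells of each sample. Ins1 stood at 0.948 and 0.447 CPM, Ins2 at 0.569 and 0.782, Gcg at 0.569 and 0.112, Sst at 2.09 and 1.12, Ppy at 0.379 and 1.01, and Ghrl at 1.90 and 1.12, in samples 1 and 2. Pyy stood at 21.8 and 0.335 CPM, with 89 of its 115 counts in sample 1 in 1 cell. The granule gene Chga stood at 1.90 and 0.894 CPM. The transcription factors Neurod1, Pax4 and Fev, which act after Neurog3, stood at 0.948 and 0.782, 0.948 and 1.12, and 3.03 and 1.68 CPM. Within trunk/duct-like cells Neurod1 had 5 counts in sample 1 and 0 in sample 2, with upper bounds of 5.15 and 3.88 CPM.

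The comparison of tip/acinar-like with trunk/duct-like cells asked how the epithelial compartments differ in this genotype. Most tested genes of the cell cycle (27 of 29) and of the unfolded protein response (14 of 15) were higher in tip/acinar-like cells, the former 22 of 29 with the unnamed cluster added to the trunk/duct-like class. Of the YAP/TEAD list 7 of 11, of junction genes 11 of 16 and of stress genes 9 of 14 were higher in trunk/duct-like cells. No list was called by camera with an estimated correlation (smallest adjusted p = 0.412), a form with 1 residual degree of freedom and little power. Of genes that did not name the classes, Asns (asparagine synthetase) and Serpini2 were higher in tip/acinar-like cells (log2 5.34 ± 0.28 and 5.27 ± 0.33). Gdnf, a neurotrophic factor, Tmem45a, Igfbp7 and Ppp1r1b were lower (log2 −5.64 ± 0.39, −5.34 ± 0.29, −4.88 ± 0.33 and −4.88 ± 0.42). In all, 2192 genes were higher and 2047 lower of 11047 tested at an adjusted p under 0.05 in edgeR, and 4193 of these 4239 went the same way in both samples. The genes were called from these same samples, so that agreement is not independent support.

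Neurog3 itself was lower in tip/acinar-like cells (log2 −3.40 ± 0.25, edgeR adjusted p = 4.78e-08, both samples). Its tip/acinar-like level (17.8 and 12.8 CPM) was no higher than that of leukocyte-like cells (19.0 and 13.8 CPM). It may therefore be background, and the size of the change may be limited by it. Of 17 tested progenitor transcription factors 10 were lower and 2 higher. Nkx6-1, a trunk and beta cell factor, had log2 −3.11 ± 0.28 and Sox4 −2.19 ± 0.16; Sox9 (−2.40) and Ptf1a (4.92) were among the markers that named the classes. Pdx1 did not differ by the test (log2 0.09 ± 0.21, edgeR adjusted p = 0.771), at 79.4 and 56.5 CPM in tip/acinar-like and 85.5 and 71.6 CPM in trunk/duct-like cells. The samples' own values were −0.11 and −0.36. They are scaled without TMM, so their sign can differ from that of the fit without the samples disagreeing. Of the duct list 14 of 15 were lower and of the acinar list 15 of 16 higher, and both lists served as markers.

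Of 29 cell cycle genes 27 were higher in tip/acinar-like cells and 0 lower, with a median log2 of 2.01, among them Ube2c (3.09), Ccna2 (3.04), Rrm2 (2.87) and Top2a (2.55). With the unnamed cluster, which holds mitotic genes, added to the trunk/duct-like class, 22 were higher and the median was 1.08. Of 11 genes of cell cycle exit 6 were lower, among them Gas1 (−2.18), Ccng2 (−2.57) and the cell cycle inhibitor Cdkn1c (−1.62), and Ccng1 was higher (1.41). Of 15 genes of the unfolded protein response 14 were higher and 0 lower, with Sdf2l1 at 3.61, Xbp1 at 2.67, Manf at 2.61 and Pdia6 at 1.80. Of 15 genes of glycolysis and hypoxia 8 were higher, including Hk2 (3.68), Car9 (3.03) and Ldha (2.37), while the angiogenic factor Vegfa was lower (−3.18).

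Of 11 tested genes of the YAP/TEAD list 7 were lower in tip/acinar-like cells and 0 higher. The list holds targets and also the factors Yap1, Wwtr1, Tead1, Tead2 and Tead4, so the count is not one of targets alone. Ctgf stood at −3.17, Amotl2 at −3.15 and Cyr61 at −2.48, and Spp1 (−6.12) was also a naming marker. Of 16 junction and keratin genes 11 were lower, among them the tight junction gene Cldn4 (−1.51), with Krt7 (−3.23) a naming marker. Of 10 genes of delamination and EMT 5 were lower, including Sparc (−4.50), Vim (−3.57) and the neuronal gene Dcx (−2.14). Of 15 Wnt pathway genes 7 were lower, including Wnt7b (−3.55), Sfrp1 (−3.73), Fzd2 (−2.28) and Tcf7l2 (−1.71), and 3 were higher. Of 18 genes of the Notch list 5 were lower, among them the receptors Notch2 (−1.87) and Notch3 (−1.67), and 4 higher. The higher genes included Id3 (3.01) and Id1 (2.11), which the list holds beside Notch receptors and ligands, so they do not by themselves show more Notch signalling. Of 14 genes of dissociation stress 9 were lower and 0 higher, with Ier3 at −3.02, Dusp1 at −2.87 and Fosb at −1.98.

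Of 18 Ngn3 target transcription factors 4 passed the filter: Cbfa2t3 was higher (1.71) and Nkx2-2 (−0.98) and Rcor2 (−0.81, edgeR adjusted p = 0.0440) were lower. Of 21 hormone and granule genes 4 passed it, with Cpe higher (3.47) and Ttr (−0.78) and Tmem27 (−2.15) lower. Adjusted over the list alone, the counts were the same but for the Ngn3 targets (2 higher and 2 lower) and the Wnt pathway (3 higher and 8 lower). camera called 10 of the 15 lists: acinar, cell cycle, unfolded protein response and glycolysis lists higher, and duct, junction, YAP/TEAD, stress, progenitor factor and EMT lists lower. None was called with an estimated correlation: the first 4 and the duct, junction and YAP/TEAD lists had an adjusted p = 0.412 with an estimated correlation, and the stress, progenitor factor and EMT lists an adjusted p = 0.560 with an estimated correlation. On 1 residual degree of freedom that form cannot decide whether the calls hold. Median, mean and test differed in sign for the hormone list (median −0.35, mean 0.15, test lower) and the Notch list (median −0.02, mean 0.06, test higher), neither of which was called. DESeq2, run without the filter on 23889 genes, called 1786 (1129 higher and 657 lower). A UMI of the acinar gene Cpa1 was held by 63.5% of trunk/duct-like cells of sample 1 and 73.0% of those of sample 2, as by 59.4% and 84.5% of leukocyte-like cells. Of 56 called genes named here, 8 had a log2 value in 1 sample over 1.5 times away from the fitted log2 value. Among them were Ppp1r1b at log2 −3.10 and −6.38 in samples 1 and 2, Ccng2 at −1.64 and −3.98, Ccng1 at 0.82 and 1.40 and Id1 at 2.47 and 0.61. The others were Cpe at 2.23 and 4.49, Cbfa2t3 at 1.63 and 1.08, Ttr at −0.74 and −1.44 and Rcor2 at −0.88 and −1.42. The limit applies to log2 values, not to folds. Genes within it could still differ in fold, such as Ptf1a (4.06 and 6.08), Gdnf (−4.78 and −6.60) and Vim (−2.99 and −4.82).

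**Figure D3:**
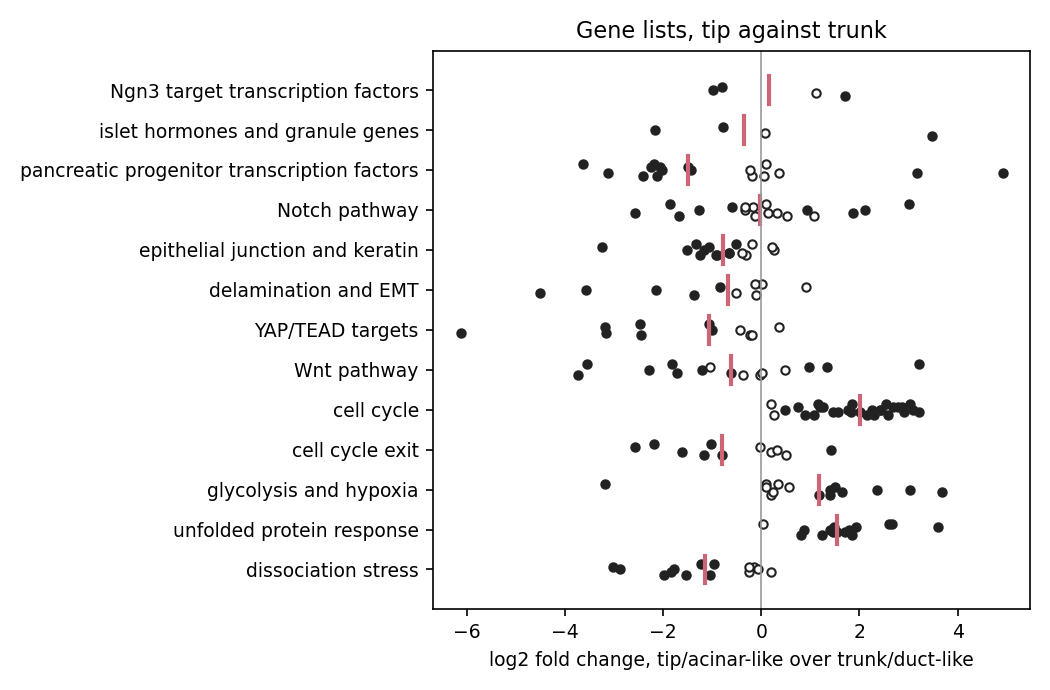
Log2 fold change of tip/acinar-like over trunk/duct-like cells (horizontal axis) for the tested members of 13 gene lists (vertical axis); filled points passed an adjusted p of 0.05 and bars are medians. The cell cycle list has a median of 2.01 (1.08 with the unnamed cluster added to trunk/duct-like cells) and the YAP/TEAD list a median of −1.05.

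Endocrine progenitor-like cells, compared with trunk/duct-like cells, held more Cacna2d1, Syt7 and Celf3 and less Vim. Cacna2d1, a calcium channel subunit, was higher (log2 5.75 ± 0.65), as were Syt7, a calcium sensor of exocytosis (4.88 ± 0.78), Celf3 (4.72 ± 0.59, at 6.09 and 3.74 in samples 1 and 2), Nnat (4.66 ± 0.76), the Notch ligand Dll3 (4.51 ± 0.74), the granule gene Scg5 (4.51 ± 0.54) and Map1b (4.45 ± 0.49). Cxcl12, Adgrg6, Hhex and Fras1 had 0 counts in these cells and were at least 8.29-, 3.66-, 3.77- and 3.69-fold lower, and Vim was lower (−4.33 ± 0.94, at −3.39 and −2.85). Insm1 (128-fold) and Cbfa2t3 (log2 2.97) were higher and Dcdc2a (−4.48), Clu (−3.75, at −2.43 and −3.63), Bicc1 (−2.68) and Atp1b1 (−2.59) lower, all of them naming markers. Neurog3 had log2 0.95 ± 0.50 and Nkx6-1 0.84 ± 0.51 (edgeR adjusted p = 0.722 for each), and Sox9 −1.86 ± 0.62 (edgeR adjusted p = 0.197, at −3.05 and −0.85), none past the threshold.

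Of 5643 genes tested 21 were higher and 24 lower, all 45 in the same direction in both samples. As the calls come from these same samples, that agreement is not independent support. The acinar gene Clps was among those higher (1.78 ± 0.46, at 3.17 and 1.29 in samples 1 and 2), at 1686 and 827 CPM against 191 and 345 CPM. camera called only the Ngn3 target list (limma, adjusted p = 0.000987, and adjusted p = 0.878 with an estimated correlation), whose 4 tested genes had all named the cluster. Of these, Insm1 and Cbfa2t3 were called, while Rcor2 (log2 1.86 ± 0.94, edgeR adjusted p = 0.722) and Nkx2-2 (−0.13 ± 0.74) were not. Adjusted over the list alone, the duct list, of marker genes, had 8 lower and 1 higher of 15 (4 lower over all genes), the progenitor factors 3 lower of 15 (0 over all genes) the Notch list 2 higher and 2 lower of 10 (1 higher over all genes) and the EMT list 2 lower of 5 (1 over all genes). The YAP/TEAD and glycolysis lists had 1 lower and the cell cycle exit list 1 higher and 1 lower, against 0 over all genes. Median, mean and test differed in sign for 6 lists, none of them called. The comparison rests on 5 and 13 cells with 11860 and 29029 counts, and no cluster was named endocrine with 2000 UMIs, doublets kept, all UMIs, another split of the UMIs or genes centred within each sample. With the first 4 of these, Insm1 and Pyy were among the top genes of an unnamed cluster or, with another split, of one named mesenchyme-like. DESeq2 called 12 genes, the fit without a filter 20, and the fit of all classes 84, and all genes shared 1 spread in the edgeR fit.

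Within the trunk/duct-like cells, clusters 6 and 7 differed in 1 of 5380 genes with sample as a block. The clusters were found without integration and largely followed the samples, with 304 and 45 cells in cluster 6 and 30 and 133 in cluster 7. The block sets aside differences between the samples, so the single call does not show that trunk/duct-like cells are alike. Dlk1, which encodes a membrane protein of the Notch ligand family, was lower in cluster 7 (log2 −1.06 ± 0.16, edgeR adjusted p = 4.45e-07, at −0.31 and −1.74 in samples 1 and 2), at 654 and 325 CPM against 815 and 1085 CPM in samples 1 and 2. Neurog3 (0.09 ± 0.30), Nkx6-1 (0.02 ± 0.29), Sox9 (0.28 ± 0.13) and Pdx1 (−0.36 ± 0.41) did not pass the test. No member of the 15 lists was called over all genes, 1 gene of the stress list was lower adjusted over the list alone, and camera called 0 lists (smallest adjusted p = 0.905; 3 lists with differing signs). The call of Dlk1 was lost in DESeq2 (0 genes, 13 at an unadjusted p under 0.05), without a filter (0, 204), without the replicate block (0, 189) and with all classes in 1 fit (0, 234), against 264 genes at an unadjusted p under 0.05 in the edgeR fit. Other clusterings paired other clusters, with 96 to 419 genes called and 0 shared with this result, and camera called the cell cycle list lower in 3 and higher with another seed (none with an estimated correlation, smallest adjusted p = 0.671).

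Trunk/duct-like cells with a Neurog3 UMI held more Cdkn1a and Cplx2 than those without. Cdkn1a, an inhibitor of the cell cycle, was higher by log2 1.17 ± 0.12, at 441 and 459 CPM against 194 and 202 CPM. Olfm1 (0.88 ± 0.21), the synaptic gene Cplx2 (0.85 ± 0.16), Gem (0.82 ± 0.20, at 1.10 and 0.42 in samples 1 and 2), Serpina6 (0.79 ± 0.19, at 0.48 and 1.32, and 0.37 ± 0.21 and not called without cells holding an Insm1 UMI) and Cited4 (0.73 ± 0.18) were also higher. Lurap1l (−0.41 ± 0.09) and the YAP target Cyr61 (−0.35 ± 0.08, at −0.20 and −0.54) were lower, as were Cym (−2.24 ± 0.31) and Nprl3 (−1.47 ± 0.36), the last chosen after its values were seen. Of 13 alternatives Cdkn1a was called in 12, Cplx2 and Lurap1l in 8, Olfm1, Gem and Cited4 in 5, Serpina6 in 4 and Cyr61 in 3, and Cym was called in 8 of 10 and Nprl3 in 2 of 12.

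Of 10242 genes tested 8 were higher, 6 of them named here, and 4 lower, in both samples. The Cym difference lay mostly in sample 1 (17.0 against 98.0 CPM, and 10.9 against 12.2 CPM in sample 2), where 127 counts fell in 34 cells and 32 of them in 1 cell. The Notch modulator Lfng missed the threshold (1.54 ± 0.39, edgeR adjusted p = 0.0501), and Sox9 (0.01), Nkx6-1 (0.03) and Pdx1 (0.07) did not pass it. Of the lists, cell cycle exit held 1 higher gene (Cdkn1a) of 10 tested and YAP/TEAD 1 lower (Cyr61) of 11; adjusted over the list alone, the Notch list had 3 higher of 16, the Ngn3 target, hormone and stress lists 1 higher, the duct and YAP/TEAD lists 2 lower and the EMT and cell cycle lists 1 lower. camera called 0 lists (smallest adjusted p = 0.153, and 0.752 with an estimated correlation), with differing signs in 3. It called the Notch list higher with 2000 UMIs, doublets kept and equal cells per decile of depth (adjusted p = 0.0183, 0.0243 and 0.0162) and the cell cycle list lower with 2000 UMIs, doublets kept and cluster 6 alone (0.00193, 0.0132 and 0.00474), none of them with an estimated correlation (0.819 to 0.885). Cells with a UMI were deeper (median 8166 against 5171 UMIs and 5331.5 against 4714), and with equal cell numbers per decile of depth, chosen after seeing the data, 13 genes were called, 8 of them shared. Without the replicate block 0 genes were called (134 at an unadjusted p under 0.05, 523 with the block) and in DESeq2 1 gene, and prior degrees of freedom were infinite, so the test rests on a spread shared by all genes.

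**Figure D4:**
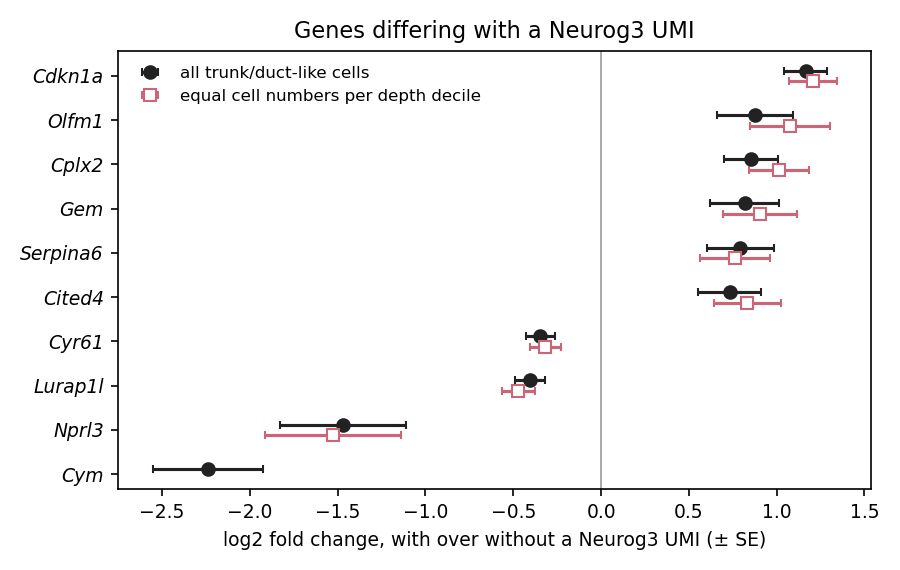
Log2 fold change ± SE (horizontal axis) of 10 of the 12 genes differing between trunk/duct-like cells with and without a Neurog3 UMI (vertical axis), for all cells and for equal cell numbers per decile of depth. Cdkn1a is at 1.17 and 1.21, and Cym has no value at equal depth.

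Between the samples, tip/acinar-like cells differed in Zg16, Sycn, Aqp12 and Baat among other genes, which were compared without a test. Zg16, Sycn, Cela3b and Cela2a, genes of zymogen granules, stood at 0.467, 48.6, 135 and 215 CPM in sample 1 and 102, 714, 1935 and 2763 CPM in sample 2. Aqp12 and Aqp8 stood at 18.7 and 30.4 CPM against 177 and 210 CPM. Baat, Mdk, Marcksl1 and Id1 were higher in sample 1, at 133, 356, 306 and 163 CPM against 31.8, 114, 110 and 58.9 CPM.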

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

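Among the alternatives, those for depth within clusters, clusters 6 and 7 alone, equal cells per decile, at least 2 Neurog3 UMIs, cells without Insm1, the unnamed cluster added, and another seed for class shares and Neurog3 levels were chosen after seeing the data; the others were fixed before. DESeq2 gave 1786 genes for tip against trunk, 12 for endocrine-like, 0 for clusters 6 and 7 and 1 for the Neurog3 UMI comparison. It was run without the edgeR filter (23889 genes against 11047 for tip against trunk), so these counts differ by test and by filter. No filter on low counts gave 20, 0 and 6 for the last 3, and all classes in 1 fit 84, 0 and 3; that fit shifted the median log2 by −0.11 (tip against trunk) and −0.13 (endocrine-like), and DESeq2 by −0.13 (endocrine-like). Without the replicate block, which sets aside the difference between samples, 2980, 44, 0 and 0 genes were called and 11 lists. With 2000 UMIs, another seed, all UMIs and doublets kept, the largest trunk clusters were other pairs of clusters and gave 205, 96, 419 and 230 genes; Dlk1 stood at 0.57 with all UMIs and 0.080 with doublets kept, and Neurog3 at −1.15 with another seed. The Neurog3 UMI comparison gave 21 genes with 2000 UMIs, 22 with doublets kept, 7 matched on depth within each cluster, 2 in cluster 6 and 2 in cluster 7; Cdkn1a was called in 12 of 13 alternatives and the other genes named in the report in 2 to 8. Mean Neurog3 over the samples' trunk/duct-like cells was 182 CPM, 145 with all UMIs and 127 at resolution 2, with sample 2 at 207, 135 and 108; its unnamed cells held 66.9, 239 and 345, those of sample 1 87.5, 73.8 and 150, and both classes added together 182, 205 and 186 in sample 2 and 144, 145 and 147 in sample 1. Class shares moved out of their interval in 22 values and stayed in 48; genes centred within each sample gave 42.2% and 44.6% tip/acinar-like cells, and 48.6% and 72.8% (27.4% and 73.1% before) with an unnamed cluster of tip/acinar markers. Lists called fell from 11 to 0 with an estimated correlation and 3 with fry. The estimated correlation rests on 1 residual degree of freedom and had little power to call any list. Of lists not called before, camera called Notch and cell cycle lists in the Neurog3 UMI comparison and duct, acinar, stress and cell cycle lists between clusters (cell cycle lower in 3, higher with another seed) in some alternatives, none with an estimated correlation. Endocrine-like cells gave no value with 2000 UMIs, doublets kept, all UMIs or another seed, since no cluster took the name, and a mesenchyme-like cluster was named only with another seed (14 and 20 cells, with Insm1, Pyy and Cacna2d1 beside collagens among its top genes and Neurog3 at 249 and 302 CPM) and at resolution 2 (7 and 3 cells). Leaving out each sample, a value with no test, left 4197 to 4235 genes of tip against trunk in their direction, 45, 1 and 12 of the others. The genes had been called from both samples, so this agreement follows in part from how they were chosen. Each sample's own value lay over 1 SE away for 87 values and within it for 27 (tip against trunk), and for 24 and 22, 4 and 6, and 11 and 17 in the others. These own values are scaled without TMM and the fit with it, so part of the distance can come from scaling. How much scaling or any other cause accounts for the changes in this section was not tested. Infinite prior degrees of freedom in 3 comparisons and samples not tied to animals limit what the p-values cover.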

Other observations

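Of the tests below, those of shared sequence and of cells with an Insm1 UMI were set before their values were seen, and those of free RNA, Neurod1 depth, equal cells per decile of depth, female cells and both sexes in sample 1 were chosen after the result was seen. The endocrine progenitor-like cells differed between the samples in Pyy, a gut and islet hormone, which had 108 counts in 4 of the 5 cells of sample 1, 89 of them in 1 cell, and 0 counts in the 13 cells of sample 2. Isl1, a factor of islet cells, stood at 4.17 and 2.35 CPM over all cells.

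Trunk/duct-like cells held Neurog3 transcripts with Neurod1 close to 0. Free RNA is argued against by a level 8.29 times that of leukocyte-like cells in the sample with the lower ratio, and shared sequence by 0% of the 31-mers in the last 500 bases of Neurog3 being found in other genes. Too few counts are argued against by a Neurod1 upper bound of at most 3.27% of the Neurog3 level. A candidate explanation is that the locus is transcribed without a working protein, but the series holds no other genotype, so no biological explanation was tested. Other reasons for low Neurod1, such as the stage of the cells, stay open.

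Genes that differed with a Neurog3 UMI, among them Cdkn1a, could follow from depth or from a few endocrine-like cells in the trunk/duct-like class. With equal cells per decile of depth the tested genes kept a median of 1.08 of their log2 change, and 8 of 11 stayed past the threshold, while Serpina6 (0.79 ± 0.19 to 0.76 ± 0.20), Cyr61 (−0.35 ± 0.08 to −0.32 ± 0.09) and Nprl3 (−1.47 ± 0.36 to −1.53 ± 0.39) kept their change at an adjusted p of 0.0860, 0.181 and 0.0528. Without the 13 and 7 cells with an Insm1 UMI they kept a median of 0.984 and 8 of 12 stayed past it: Serpina6 (to 0.37 ± 0.21) lost most of its change, while Cited4 (to 0.71 ± 0.18), Olfm1 (to 0.86 ± 0.22) and Cyr61 (to −0.34 ± 0.08) kept theirs, at an adjusted p of 0.0965, 0.0687 and 0.0532. The values argue against both as the whole cause, with Serpina6 as the exception for the second and Cym not tested for the first. No biological explanation was tested, and the state of the cells that hold Neurog3 stays open.

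Xist is made by the inactive X chromosome of female cells. In sample 1 it stood at 1279 CPM in tip/acinar-like, 1726 CPM in trunk/duct-like and 638 CPM in leukocyte-like cells. In sample 2 it stood at 572 CPM in tip/acinar-like cells, 23.2 CPM in trunk/duct-like cells and 30.3 CPM in leukocyte-like cells. Free RNA is argued against by the ratio of 18.9 to leukocyte-like cells (10.5 to 37.8), and 0 of 20 acinar genes shared a 31-mer with Xist, though inexact, antisense or unannotated matches stay open. Female cells among the tip/acinar-like cells stay open: the Y-linked level in cells with 2 or more Xist UMIs was 1.04 times that of cells with none (0.844 to 1.31), but the latter were shallower (median 6390 against 9850.5 UMIs), so they may be cells whose Xist was missed, and the class held 147 Y-linked CPM against 261 in trunk/duct-like and 245 in leukocyte-like cells. Of the 700 tip/acinar-like cells of sample 2 with a Xist UMI, 463 also held a Y-linked UMI. Female cells do not make Y-linked RNA, but free Y-linked RNA was not measured, so these counts do not settle the question. In trunk/duct-like cells of sample 1 the Y-linked ratio of cells with 2 or more Xist UMIs to cells with none was 0.469 (0.357 to 0.620). The whole interval lies below 1, so cells with 2 or more Xist UMIs held less Y-linked RNA per UMI than cells with none. Both sexes may therefore be present in that sample, although 133 of its 271 trunk/duct-like cells with a Xist UMI also held a Y-linked UMI. The bound of 0.5, set with the value known, lies inside the interval, so the test at that bound did not decide. With 5 or more Xist UMIs, a limit also picked after the values were seen, the ratios were 1.07 and 0.341 (0.252 to 0.462), and no biological explanation was tested.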
